A study of Homo sapiens with 12 samples.

How the data were processed

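RNA sequencing of total RNA, depleted of ribosomal RNA, was made from 12 libraries: 2 human cell lines, 688(A)T and 839T, each transfected for 72 hours with a control siRNA pool or with siRNAs against B7-H3, with 3 libraries per group. Per the labels, RNA had an integrity number of at least 7.0 and an amount of at least 500 ng. The processing notes name STAR, featureCounts, Subread 1.4.6-p5, edgeR 3.30, R 4.0.2 and GRCh38. The strand setting, the annotation release and the filters are not given in the sources used here.

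The authors deposited a table of counts, raw and whole-numbered, for 60725 Ensembl genes, and a table of log2 values for 12101 genes. The deposited log2 values equal log2 CPM, computed here with TMM factors and a prior count of 0.5, to within 0.012. In both tables the header lacks a name for the gene ID column, so its 12 names belong to the value columns 1 place further right. All value columns were used. Gene symbols were found by stable ID for 56558 genes and coordinates, from GENCODE 29, for 57055. The 50 copies of pseudoautosomal genes on the Y chromosome held 53 counts in all. Of the tested genes, 6 share a symbol with another.

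Library totals ran from 28259253 to 52156716 counts, and 32784 genes had at least 1 count. The edgeR function filterByExpr kept 15704 genes, and 45021 were not tested. TMM normalization factors lay between 0.955 and 1.049 and the common biological coefficient of variation was 0.037. Counts of replicates were checked against each other within each group, and no library was a copy of another in its group. Control replicates 1 and 2 of 688(A)T were the closest pair, with a chi-square per gene of 1.868. Against control replicate 3 they gave 6.109 and 6.025. The labels do not say that replicate numbers pair the libraries, and no pairing was used.

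All 12 libraries were fitted together in 4 groups with edgeR 4.0.16 (quasi-likelihood fit, robust, 8 residual degrees of freedom) under R 4.3.3. Contrasts were siB7H3 against siControl in each line, the average of both, the difference between lines (the effect in 839T minus that in 688(A)T) and 839T against 688(A)T among controls. Adjusted p-values are Benjamini-Hochberg over all tested genes in a contrast, and genes under 0.05 are called risen or fallen. CPM are scaled by TMM. CD276 was also tested by an exact permutation test of CPM. Overlaps were tested with Fisher's exact test.

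Gene lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over 23 lists, and again with a correlation estimated per list and with fry. The lists were checkpoint ligands, Wnt targets, Wnt antagonists, interferon-stimulated genes, MHC class I, cytokines and NF-kB targets, S phase, G2/M, p53 targets, cholesterol synthesis, glycolysis and hypoxia, the unfolded protein response and ATF4 targets, matrix, proteases, targets of TGF-beta, SRF and YAP, MAPK feedback, JAK/STAT3 targets, apoptosis, autophagy and lysosome, histones, ribosomal proteins, mitochondrially encoded mRNAs and RNA interference. A further 7 marker sets stood for cell types. Counts of list members are given over all tested genes and adjusted over the list alone.

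Lists, contrasts, the rule for named genes and most alternatives were set before the data were examined. Named were CD276, the 12 highest and 12 lowest genes per line, the 10 highest and 10 lowest in both lines, the 6 highest and 6 lowest differences between lines, the 8 highest and 8 lowest between control lines, and up to 4 members per list with the smallest adjusted p. Genes named by size had a mean of at least 5 CPM in a group (for genes changed in both lines, in each line) and a standard symbol. Those ranked per line or between control lines also had no overlap between the 3 and 3 libraries. Some genes that meet the rule are not reported here. Sex-linked marker genes were left out of the named genes. List members beyond that rule were named after their values were seen, where a count was 5 or fewer or a member moved against its list. Folds against a group with 0 counts are lower bounds against 3 counts over the group.

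The alternatives were the DESeq2 1.42.0 Wald test, DESeq2 size factors in edgeR, upper-quartile factors, no low-count filter, at least 1 CPM in 3 libraries, each line fitted alone, a replicate block, limma-trend on the deposited log2 values, each library left out in turn, an adjusted p under 0.01, and both other list tests. Chosen after seeing the data were thinning of every library to the smallest total, removal of a trend with gene length and GC content (11136 genes used), and leaving out genes with CGATAC in a transcript. Sites that could pair with an siRNA seed were sought as heptamers in 3 prime UTRs of at least 50 nucleotides, with at least 50 carriers each, over 10260 genes.

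The tests were tested on simulated data with the groups' own depth. Changed genes were drawn only from those with a mean of at least 5 CPM. In 688(A)T edgeR recovered 94.0% of genes changed 1.25-fold and 100.0% of those changed 2-fold, and 2.4% of its calls were unchanged genes. In 839T these were 84.0%, 100.0% and 6.4%, and for the difference between lines 64.0%, 99.0% and 5.0%. A list of 30 genes changed 1.1-fold had camera adjusted p-values of 6.49e-15 with the preset and 7.09e-04 with an estimated correlation, and 0 other lists were called. Simulated genes were drawn independently, whereas members of real lists were correlated (0.714 estimated for interferon-stimulated genes). The simulation therefore cannot show how the preset test behaves on correlated lists. Nor can it show the share of false calls in real data, where genes vary together between libraries. Recovery of less abundant genes, or of single genes changed less than 1.25-fold, was not measured.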

Results

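The transcriptomes of 2 human cell lines, 688(A)T and 839T, were measured by RNA sequencing 72 hours after transfection with a control siRNA pool or with siRNAs against B7-H3. B7-H3 is an immune checkpoint protein of the B7 family, encoded by CD276. The series describes both lines as metastatic melanoma lines picked for their high B7-H3, and asks which functions and downstream effectors B7-H3 has. Each of the 4 groups held 3 libraries, 12 in all. Total counts were 45505239, 42476733 and 50059431 in the control libraries of 688(A)T (replicates 1, 2 and 3) and 28752356, 28259253 and 31222881 in its siB7H3 libraries. In 839T they were 34687450, 29777852 and 31749569 in the controls and 44287566, 52156716 and 30584206 with siB7H3. Of 60725 annotated genes, 15704 had enough counts to be tested. The labels do not say whether replicates were separate cultures, so every p-value below measures the spread between these libraries, part of which could be technical only. Values after ± are the SD over n = 3 libraries and SE is the standard error of a fitted log2 fold change. Some list members were named after their values were seen, because a count was 5 or fewer or because they moved against their list (ELN, SPRY1, CCL2, ZMAT3, INSIG1 and ID3 among them).

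The siRNAs lowered CD276 about equally in both lines, which addresses whether the target was reached. In 688(A)T, CD276 mRNA was 186 ± 4.08 CPM (counts scaled to library size) in the control group and 13.4 ± 0.737 CPM with siB7H3 (SD, n = 3 each), which left 7.22% of the control level. In 839T it was 214 ± 11.1 CPM in the control group and 16.3 ± 0.302 CPM with siB7H3 (SD, n = 3 each), which left 7.62%. The log2 fold changes were -3.79 (SE 0.05) and -3.71 (SE 0.05), 13.8-fold and 13.1-fold lower, with edgeR adjusted p-values of 4.68e-30 and 1.71e-30. The effect differed between lines by 0.08 (SE 0.07, adjusted p = 0.63). CD276 (ENSG00000103855.17) lies on chromosome 15 at 73683966 to 73714518 of GRCh38, on the plus strand. In each line all 3 siB7H3 libraries lay below all 3 control libraries, and an exact two-sided permutation test of CPM gave p = 0.1, the smallest that 3 against 3 libraries allow.

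**Figure D1:**
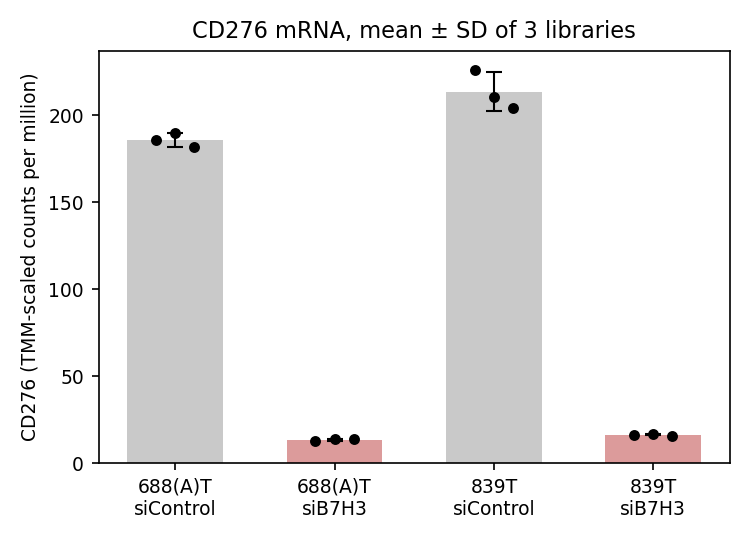
CD276 mRNA in TMM-scaled CPM (vertical axis) in the 4 groups of line and siRNA; bars are means, error bars SD and points the 3 libraries of each group. The control libraries sit between 181.7 and 225.8 CPM and the siB7H3 libraries between 12.6 and 16.5 CPM.

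Genes ranked by size in each line were those with a mean of at least 5 CPM in a group and no overlap between groups. Of these, the ones that rose most in 688(A)T were led by the cytokine IL24 and by genes of the antiviral interferon response. IL24 went from 6.52 ± 1.13 to 20.7 ± 4.48 CPM (n = 3 each), a log2 fold change of 1.67 (SE 0.18, adjusted p = 2.93e-04). RSAD2, which encodes the antiviral protein viperin, rose by 1.36 (SE 0.24, adjusted p = 0.00674) from 36.8 ± 11.2 CPM. HERC5, the ligase for the ubiquitin-like modifier ISG15, rose by 1.27, OASL by 1.14, the nucleotide kinase CMPK2 by 0.96 and IFIT2 by 0.90. Outside the interferon response, the endothelial proteoglycan gene ESM1 rose by 1.06, the retinoic acid-induced receptor GPRC5A by 0.91 (SE 0.07, adjusted p = 2.05e-10) and the lipid enzyme GPAT3 by 0.86. CXCL8, which encodes the neutrophil chemokine interleukin-8, rose by 0.84, the interferon-inducible membrane protein BST2 by 0.80 and the YAP target ANKRD1 by 0.79.

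Among genes with that floor and no overlap, the largest fall in 688(A)T after CD276 was that of HCCS, the enzyme that attaches heme to cytochrome c, from 31.8 ± 0.233 to 11.9 ± 1.6 CPM (log2 fold change -1.41, SE 0.07, adjusted p = 1.98e-13). P3H1, a collagen prolyl hydroxylase, fell from 210 ± 3.12 to 111 ± 8.31 CPM (-0.92, SE 0.05, adjusted p = 3.80e-14). The myelin basic protein gene MBP changed by -0.95, the matrix protein gene DPT by -0.87, DIPK1A by -0.82, the endothelial junction gene JCAD by -0.77 and the RING finger gene LONRF1 by -0.71. ATP6AP1, an accessory subunit of the vacuolar proton pump, fell from 110 ± 3.6 to 67.8 ± 2.79 CPM (-0.70, SE 0.05). The growth factor receptor gene FGFR2 changed by -0.69, and the growth factor gene PDGFD, the Wnt antagonist gene SFRP4 and PLXDC2 each by -0.67. HCCS lies on chromosome X at 11111301 to 11123078 and ATP6AP1 on chromosome X at 154428632 to 154436516. Among these genes HCCS, P3H1, MBP, JCAD and LONRF1 carry the heptamer GCGATAC in a 3 prime UTR, and DIPK1A elsewhere in a transcript. The heptamer also lies in the CD276 mRNA, and pairing of an siRNA through it is weighed further below.

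Among immune gene lists fixed before the data were examined, the interferon list moved most in 688(A)T. Of 38 interferon-stimulated genes tested, 31 rose and 0 fell (36 and 0 adjusted over the list alone), with a median log2 fold change of 0.45 and all 38 estimates above 0. Examples with the smallest adjusted p were the helicase gene DDX60L at 0.47 (SE 0.04), the transcription factor gene IRF7 at 0.51 (SE 0.06) and the ADP-ribosyltransferase gene PARP14 at 0.44 (SE 0.05). The list's camera adjusted p was 7.77e-24, and adjusted p = 0.274 with an estimated correlation. Control replicate 3 had the lowest mean of these genes among the 688(A)T libraries, and without it the list's median was 0.36 and 28 genes rose. Of 21 genes for antigen presentation on MHC class I, 5 rose and 1 fell (8 and 1 adjusted over the list alone): the peptide transporter genes TAP1 (0.29) and TAP2 (0.30), the transactivator gene NLRC5 (0.28), PSMB8 and TAPBP rose, and the folding enzyme gene PDIA3 (-0.18) fell. This list had a median of 0.10 and a camera adjusted p of 6.94e-04, and adjusted p = 0.322 with an estimated correlation. Of 25 cytokine, chemokine and NF-kB target genes, 9 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.31 and adjusted p = 4.89e-05, or adjusted p = 0.162 with an estimated correlation. The anti-apoptotic NF-kB target BIRC3 rose by 0.63 (SE 0.11) and the antioxidant gene SOD2 by 0.25 (SE 0.05), while the monocyte chemokine gene CCL2 fell by 0.45. Of 17 genes of the RNA interference machinery and double-stranded RNA sensing, 6 rose and 0 fell (7 and 1 adjusted over the list alone), among them the RNA editing gene ADAR (0.21), TNRC6C (0.32) and the kinase gene EIF2AK2 (0.16), whose call was lost without control replicate 3 (adjusted p = 0.152) or siB7H3 replicate 3 (0.0527). Their median was 0.11 and their camera adjusted p 0.00181, and adjusted p = 0.162 with an estimated correlation.

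More cell cycle genes rose than fell in 688(A)T. More fell than rose among ribosomal protein genes, matrix genes and targets of TGF-beta, SRF and YAP. Of 35 S phase genes, 18 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 0.16 and a camera adjusted p of 2.55e-09, and adjusted p = 0.285 with an estimated correlation. The cell cycle transcription factor gene E2F1 rose by 0.29, the licensing factor gene CDT1 by 0.32 and the replicative helicase gene MCM5 by 0.19. Of 35 G2/M genes, 15 rose and 0 fell (21 and 0 adjusted over the list alone; median 0.12, adjusted p = 9.68e-09, or adjusted p = 0.309 with an estimated correlation), among them the mitotic kinase gene AURKA (0.21), the phosphatase gene CDC25B (0.24) and the proliferation marker MKI67 (0.30). Of 34 cytosolic ribosomal protein genes, 0 rose and 21 fell (0 and 26 adjusted over the list alone), such as RPL13 (-0.20), RPS3 (-0.21) and RPL34 (-0.21), with a median of -0.14 and adjusted p = 5.16e-11, or adjusted p = 0.285 with an estimated correlation. Across 11136 genes, which are not independent replicates, the log2 fold change in 688(A)T rose with transcript length (Spearman 0.20), and ribosomal protein mRNAs are short. Of 28 fibrillar collagen and matrix genes, 13 fell and 1 rose (14 and 1 adjusted over the list alone; median -0.16, adjusted p = 5.73e-07, or adjusted p = 0.309 with an estimated correlation). The elastic fibre gene FBLN5 fell from 120 ± 9.15 to 80 ± 8.07 CPM (-0.59) and the adhesion modulator gene TNC from 984 to 820 CPM (-0.26), and ELN, which encodes elastin, rose by 0.19. Fibroblast markers moved with them: 10 of 16 fell and 0 rose (13 and 0 adjusted over the list alone; median -0.24), and COL1A1, COL1A2, COL3A1 and FBLN1 stand in both lists. Of 28 targets of TGF-beta, SRF and YAP, 10 fell and 2 rose (12 and 2 adjusted over the list alone; median -0.11, adjusted p = 0.00169, or adjusted p = 0.309 with an estimated correlation). The matrix protein gene TGFBI (-0.32) and the actin-binding gene CALD1 (-0.38) fell, while ANKRD1 (0.79) and ID3 (0.13) rose.

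Cholesterol synthesis and MAPK lists also passed in 688(A)T. Of 25 cholesterol synthesis genes, 5 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.08, camera adjusted p = 0.00376, or adjusted p = 0.162 with an estimated correlation): LSS (-0.15) and FDFT1 (-0.14) were among those that fell, and the sterol sensor regulator INSIG1 (0.16) rose. The LSS call was lost without control replicate 3 (adjusted p = 0.0818), and without siB7H3 replicate 1 those of FDFT1 (0.0513) and INSIG1 (0.0848). Of 25 MAPK feedback and immediate early genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone, 6 and 0 by DESeq2; median 0.05, adjusted p = 0.0363, or adjusted p = 0.343 with an estimated correlation). The phosphatase genes DUSP5 and DUSP6 each rose by 0.32 and IER3 by 0.28, and the inhibitor gene SPRY1 changed by -1.14 (adjusted p = 0.0231), a fall that DESeq2 did not call. The MAPK call was lost without control replicate 2 (adjusted p = 0.128), siB7H3 replicate 1 (0.085) or siB7H3 replicate 2 (0.0729). The other lists did not pass in this line, though histone genes passed under 9 of the alternatives tried and matrix proteases and inhibitors under 8. These were p53 targets (28 tested, 5 rose and 1 fell, 7 and 1 adjusted over the list alone, adjusted p = 0.25), glycolysis and hypoxia targets (26 tested, 1 rose and 6 fell, the same numbers adjusted over the list alone, adjusted p = 0.099), and the unfolded protein response with ATF4 targets (28 tested, 5 rose and 3 fell, 7 and 3 adjusted over the list alone, adjusted p = 0.841). Matrix proteases and inhibitors gave 10 rises and 2 falls among 23, unchanged adjusted over the list alone, with the urokinase gene PLAU at 0.39 and adjusted p = 0.0593. JAK/STAT3 targets gave 3 rises and 2 falls among 18 (3 and 3 adjusted over the list alone), SOCS2 at -0.30, and adjusted p = 0.841. Apoptosis regulators gave 5 rises and 0 falls among 25 (7 and 3 adjusted over the list alone, adjusted p = 0.0628), and autophagy and lysosome genes 3 rises and 1 fall among 27 (5 and 2 adjusted over the list alone, adjusted p = 0.374). Of 13 histone genes 2 rose, H2BC5 and H1-2, and of 13 mitochondrially encoded mRNAs 2 fell, MT-ND3 and MT-CO3, with the same numbers adjusted over the list alone, medians of 0.16 and -0.11 and adjusted p-values of 0.0505 and 0.194. These gene calls depended on single libraries. That of MT-CO3 was lost in 7 of the 12 omissions of a library (adjusted p from 0.053 to 0.177), and that of MT-ND3 without siB7H3 replicate 1 (0.0712) or 2 (0.092). H2BC5 lost its call without control replicate 1 (0.0642) or 3 (0.121) or siB7H3 replicate 3 (0.103), and H1-2 without control replicate 3 (0.106) or siB7H3 replicate 3 (0.219).

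To ask how many genes responded in 688(A)T, all tested genes were counted at a Benjamini-Hochberg adjusted p below 0.05 in edgeR. There were 2368 such genes, 1111 higher and 1257 lower, with a median absolute log2 fold change of 0.21, and 37 of them changed at least 2-fold. With no low-count filter 795 were higher and 1750 lower. Without control replicate 3 the count was 1248, and without siB7H3 replicate 1 it was 1417. Leaving out the same libraries also ended the CXCL8 call (adjusted p = 0.0916 and 0.0832), as did leaving out siB7H3 replicate 2 (0.0715), and the BST2 call was lost in 10 of the 12 omissions (adjusted p from 0.0539 to 0.116). Where edgeR called 0 genes of a list in a direction in this line, the numbers at an unadjusted p under 0.05 and by DESeq2 were 0 and 0 for interferon, S phase, G2/M and histone genes lower and for ribosomal and mitochondrially encoded genes higher. They were 3 and 1 for apoptosis regulators lower, and 1 and 0 for RNA interference genes and for checkpoint ligands lower.

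In 839T, CXCL8 rose most among the called genes with a mean of at least 5 CPM in a group and no overlap between groups. CXCL8 (chromosome 4, 73740506 to 73743716) went from 14.1 ± 1.2 to 31.5 ± 5.76 CPM (n = 3 each), a log2 fold change of 1.18 (SE 0.18, adjusted p = 0.00468). PMAIP1, which encodes the pro-apoptotic protein NOXA, rose from 24.3 ± 3.88 to 47.1 ± 7.37 CPM (0.96, SE 0.17). The stress-induced transcription factor gene ATF3 rose by 0.71 (SE 0.07, adjusted p = 8.95e-08), BIRC3 by 0.71 (SE 0.08) and IFIT2 by 0.74 (SE 0.10) from 147 ± 17.9 CPM. The small GTPase gene RRAD rose by 0.77 and EVI2A by 0.75. The matrix protease gene MMP3 (0.99), the collagen receptor gene ITGA2 (0.81), OASL (0.78) and RAB27B (0.67) passed by less. The MMP3 call was lost without control replicate 2 or 3 or siB7H3 replicate 1 or 2 (adjusted p from 0.0519 to 0.0694). Those of ITGA2, OASL and RAB27B were lost in 5, 10 and 8 of the 12 omissions of a library (adjusted p up to 0.101, 0.132 and 0.141).

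Among genes with that floor and no overlap, HCCS again had the largest fall after CD276, from 39.6 ± 2.5 to 16 ± 1.2 CPM (log2 fold change -1.30, SE 0.07, adjusted p = 3.02e-13). ATP6AP1 fell from 116 ± 2.12 to 69.2 ± 6.04 CPM (-0.75, SE 0.05). IRAG1, a mediator of nitric oxide signalling in smooth muscle, changed by -0.88, and the matrix genes MXRA5 and SVEP1 by -0.85 and -0.68. The adhesion receptor gene TENM2 changed by -0.73, LONRF1 by -0.68 and the guidance factor gene SLIT3 by -0.66, from 127 ± 4.1 to 80.3 ± 5.22 CPM. LGR5, a Wnt target and receptor, OLFML1 and the Wnt antagonist gene SFRP2 each changed by -0.65. Of the genes named here, HCCS, LONRF1 and SVEP1 carry the GCGATAC heptamer in a transcript. The myosin light chain gene MYL9 changed by -0.68, but its call was lost in 10 of the 12 omissions of a library (adjusted p from 0.0536 to 0.145).

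In 839T more matrix genes fell than rose. Of 28 fibrillar collagen and matrix genes, 20 fell and 0 rose (24 and 0 adjusted over the list alone), with a median of -0.27. TNC fell from 825 to 610 CPM (-0.44, SE 0.04), the proteoglycan gene BGN from 65.1 to 48.3 CPM (-0.43) and THBS2 from 184 to 142 CPM (-0.38). The camera adjusted p was 4.97e-15, and adjusted p = 0.25 with an estimated correlation. Fibroblast markers again moved with them, 9 of 16 falling and 1 rising (10 and 1 adjusted over the list alone; median -0.20). Of 28 targets of TGF-beta, SRF and YAP, 11 fell and 2 rose, also adjusted over the list alone, with LTBP2 at -0.26, CALD1 at -0.28 and TGFBI at -0.23 among those that fell and ANKRD1 (0.41) and ID2 (0.18) rising. Their median was -0.13 and adjusted p = 0.00348, or adjusted p = 0.446 with an estimated correlation. Of 13 mitochondrially encoded mRNAs, 4 fell (5 adjusted over the list alone; median -0.22, adjusted p = 0.00225, or adjusted p = 0.446 with an estimated correlation), namely MT-ND3 (-0.49), MT-CO1 (-0.49), MT-CO2 (-0.39) and MT-CO3 (-0.46). Without control replicate 3 this list had adjusted p = 0.0957. Genes of the mitochondrial genome held 0.0588 to 0.0729% of counts in the 839T controls and 0.0483 to 0.0541% with siB7H3. Over the 688(A)T libraries they held 0.0427 to 0.0508%. How much of these mRNAs the library preparation kept was not measured, so their fall may be partly technical. Of 28 genes of the unfolded protein response and ATF4 programme, 10 fell and 3 rose (12 and 4 adjusted over the list alone; median -0.09, adjusted p = 0.00506, or adjusted p = 0.308 with an estimated correlation). The serine synthesis genes PSAT1 (-0.46) and PHGDH (-0.30) and the mTORC1 inhibitor gene DDIT4 (-0.57) fell, while ATF3 rose.

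Among cytokine and NF-kB targets, p53 targets and apoptosis regulators, more genes rose than fell in 839T. Of 25 cytokine, chemokine and NF-kB target genes, 12 rose and 1 fell (18 and 3 adjusted over the list alone), among them the inflammatory cytokine gene IL1B (0.84, SE 0.13), SOD2 (0.54, SE 0.05) and the NF-kB inhibitor gene NFKBIA (0.25), with a median of 0.26. The camera adjusted p was 4.78e-05, and adjusted p = 0.127 with an estimated correlation. Of 28 p53 targets, 8 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.07): the exonuclease gene AEN rose by 0.29, TP53INP1 by 0.37, the cell cycle inhibitor gene CDKN1A by 0.24 and the p53 ligase gene MDM2 by 0.22, and ZMAT3 fell by 0.25. Of 25 apoptosis regulators, 7 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.11), with HRK, which encodes a BH3-only killer protein, at 1.31 (1.58 to 3.93 CPM), PMAIP1 at 0.96 and the inhibitor gene BIRC2 at 0.20. These lists had camera adjusted p-values of 0.00109 and 0.001, and each had adjusted p = 0.047 with an estimated correlation. Of 27 autophagy and lysosome genes, 4 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.07, adjusted p = 3.89e-04, or adjusted p = 0.25 with an estimated correlation), namely the autophagy receptor gene SQSTM1 (0.45), the lysosomal channel gene MCOLN1 (0.39), ATG14 (0.21) and ATP6V1H (0.18). Of 25 MAPK feedback and immediate early genes, 7 rose and 0 fell (10 and 0 adjusted over the list alone; median 0.06, adjusted p = 0.00803, or adjusted p = 0.446 with an estimated correlation), including DUSP5 (0.29) and IER3 (0.29), and without siB7H3 replicate 2 this list had adjusted p = 0.0696.

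Cell cycle and interferon genes had smaller medians in 839T. The difference between lines had a camera adjusted p of 5.09e-14 for interferon, 0.00301 for S phase and 0.0393 for G2/M genes, or adjusted p = 0.42, 0.599 and 0.757 with an estimated correlation. Of 35 G2/M genes, 9 rose and 2 fell (12 and 2 adjusted over the list alone; median 0.06, camera adjusted p = 0.00109, or adjusted p = 0.545 with an estimated correlation), with the cyclin-dependent kinase subunit gene CKS2 at 0.24 and MKI67 at -0.24. The MKI67 call was lost without control replicate 1 (adjusted p = 0.0516), control replicate 3 (0.0892) or siB7H3 replicate 3 (0.0795). Of 35 S phase genes, MCM2, MCM7 and PCNA rose and 0 fell, also adjusted over the list alone (median 0.07, adjusted p = 0.00407, or adjusted p = 0.545 with an estimated correlation). The MCM7 call was lost without control replicate 2 (adjusted p = 0.12), siB7H3 replicate 1 (0.126) or siB7H3 replicate 2 (0.058). Of 38 interferon-stimulated genes, 4 rose and 0 fell (8 and 0 adjusted over the list alone, 9 and 0 by DESeq2, 13 and 1 at an unadjusted p under 0.05), namely IFIT2, OASL, whose call was lost in 10 of the 12 omissions, IFI44 (0.29) and DDX60 (0.27), with a median of 0.10 and adjusted p = 0.00109, or adjusted p = 0.589 with an estimated correlation. Without control replicate 3, which again had the lowest mean of these genes, adjusted p was 0.0863. The remaining lists did not pass. MHC class I genes gave 1 rise (ERAP2) and 1 fall (PDIA3) among 21 (1 and 2 adjusted over the list alone, adjusted p = 0.981), and cholesterol synthesis genes 1 rise (INSIG1, 0.56) and 2 falls (LSS at -0.14 among them, a call lost without control replicate 1, adjusted p = 0.164, or siB7H3 replicate 3, 0.156) among 25 (also adjusted over the list alone, adjusted p = 0.955). Glycolysis and hypoxia targets gave 2 rises and 4 falls among 26 (2 and 5 adjusted over the list alone, adjusted p = 0.272), and matrix proteases and inhibitors 7 rises and 4 falls among 23 (7 and 5 adjusted over the list alone, adjusted p = 0.177), with ADAMTS5 and PLAU each at 0.55 and MMP14 at 0.22. JAK/STAT3 targets gave 5 rises and 1 fall among 18 (6 and 1 adjusted over the list alone, adjusted p = 0.286), with the kinase gene PIM1 at 0.42. Histone genes gave 2 rises (H1-2 and H2BC5) among 13 (4 adjusted over the list alone, 0 by DESeq2, adjusted p = 0.317). The H1-2 call was lost in 7 of the 12 omissions of a library (adjusted p from 0.0515 to 0.187), and that of H2BC5 without control replicate 3 (0.224), siB7H3 replicate 2 (0.136) or siB7H3 replicate 3 (0.082). There were also 1 fall (RPL8) among 34 ribosomal protein genes (0 adjusted over the list alone, adjusted p = 0.21) and 1 fall (AGO1) among 17 RNA interference genes (also adjusted over the list alone, adjusted p = 0.675).

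**Figure D2:**
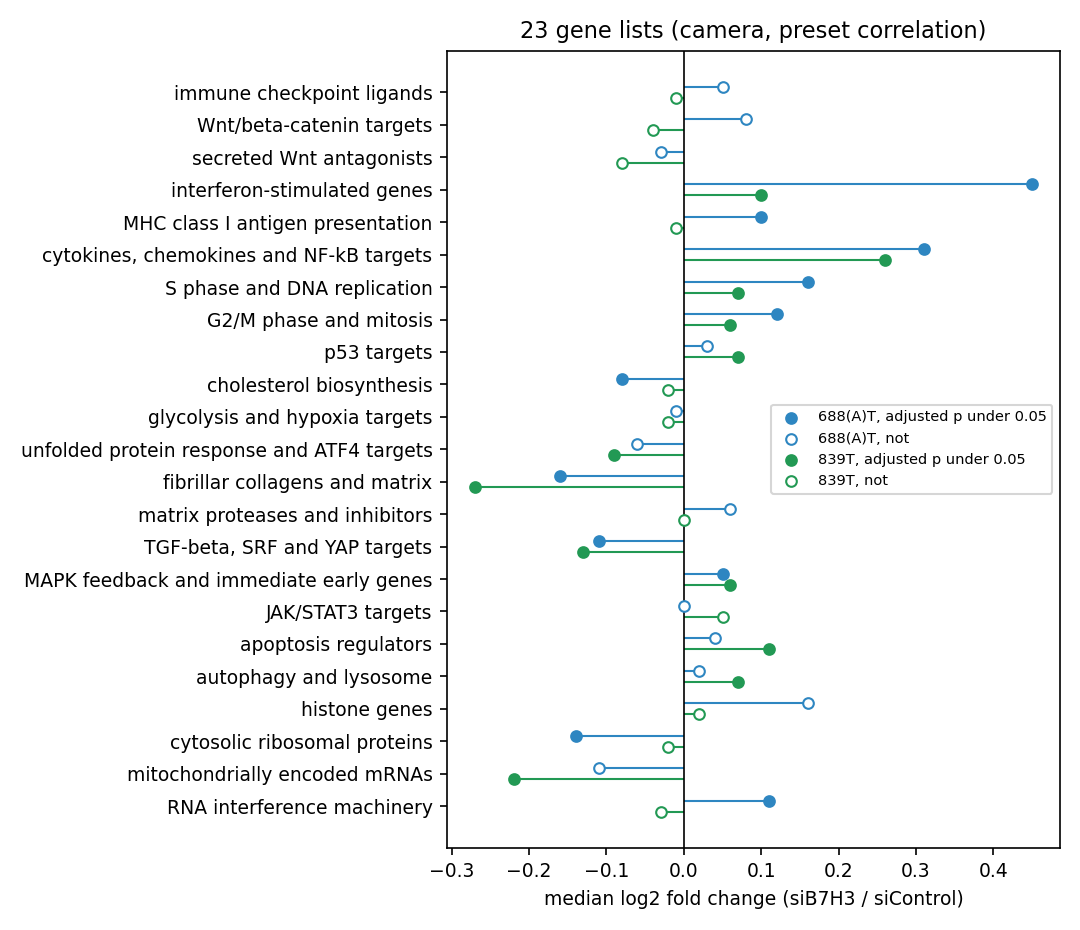
Median log2 fold change, siB7H3 over siControl, of the members tested in each of 23 gene lists (horizontal axis, log2) in 688(A)T (blue) and 839T (green); filled points mark lists with a camera adjusted p under 0.05 at the preset correlation. Interferon-stimulated genes sit at 0.45 in 688(A)T and 0.10 in 839T, and matrix genes at -0.16 and -0.27.

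In 839T, 1847 genes changed at the same threshold, 808 higher and 1039 lower, with a median absolute log2 fold change of 0.22, and 29 of them changed at least 2-fold. With no low-count filter 1023 were higher and 974 lower. Without siB7H3 replicate 1 the count was 944, and without control replicate 3 it was 1218. Across 11136 genes, which are not independent replicates, the log2 fold change in 839T fell with GC content (Spearman -0.28). With the length and GC trend removed, 2066 genes changed. Where edgeR called 0 genes of a list in a direction in this line, the numbers at an unadjusted p under 0.05 and by DESeq2 were 0 and 0 for matrix, mitochondrially encoded and ribosomal protein genes and Wnt antagonists higher and for S phase, apoptosis, autophagy, MAPK and histone genes lower. They were 1 and 0 for interferon-stimulated genes lower and RNA interference genes higher, and 2 and 0 for Wnt targets higher.

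Because the series names CD47 and beta-catenin beside B7-H3, checkpoint ligands and the Wnt pathway were examined in both lines. CD47, the macrophage "do not eat me" signal, did not pass in either line: it was 183 and 178 CPM in 688(A)T (log2 fold change -0.04, SE 0.04, adjusted p = 0.542) and 221 and 222 CPM in 839T (0.01, SE 0.04, adjusted p = 0.952), control before siB7H3. CD274, which encodes PD-L1, rose from 17.4 to 21 CPM in 688(A)T (0.28, SE 0.08, adjusted p = 0.0322) and from 6.06 to 8.26 CPM in 839T (0.45, SE 0.12, adjusted p = 0.0152), and PDCD1LG2, which encodes PD-L2, rose by 0.17 and 0.15. Of 15 ligands tested, 4 rose and 0 fell in 688(A)T, where LGALS9 (0.69, from 2.47 to 3.96 CPM; interaction adjusted p = 0.126) and BTN3A1 (0.20) also passed. In 839T 2 rose and 1 fell, VSIR (-0.27), which encodes VISTA. The counts were the same adjusted over the list alone, and the list did not pass in either line (camera adjusted p = 0.211 and 0.768). The CD274 call was lost in 688(A)T without control replicate 3 (adjusted p = 0.153), siB7H3 replicate 1 (0.173) or siB7H3 replicate 2 (0.105), and in 839T without control replicate 3 (0.0735) or siB7H3 replicate 1 (0.0802). That of PDCD1LG2 was lost in 688(A)T without control replicate 3 (0.0626) or siB7H3 replicate 1 (0.0544), and in 839T without control replicate 1 (0.0867) or 3 (0.102) or siB7H3 replicate 1 (0.0862) or 3 (0.0752).

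Among 14 Wnt/beta-catenin targets, the cyclin gene CCND1 (0.24, SE 0.04) and FOSL1 (0.52, SE 0.10) rose in 688(A)T and the receptor gene TNFRSF19 (-0.29) fell, 2 and 1 also adjusted over the list alone, with a median of 0.08 and camera adjusted p = 0.243. In 839T LGR5 (-0.65), the feedback inhibitor gene AXIN2 (-0.69) and the transcription factor gene TCF7 (-0.39) fell and 0 rose (4 and 1 adjusted over the list alone). The median was -0.04, the mean 0.02 and the camera adjusted p 0.317. That mean includes APCDD1 at 2.51, a gene with 0 CPM in the 839T controls and at most 0.03 CPM with siB7H3. The difference between lines had a median of -0.17 (camera adjusted p = 0.046, or adjusted p = 0.248 with an estimated correlation), and 7 of the 12 omissions of a library ended that call (adjusted p from 0.0544 to 0.112). Among 10 secreted Wnt antagonists and their receptors, SFRP4 (-0.67) and DKK2 (-0.56, from 39.3 to 26.6 CPM) fell and DKK1 (0.28, from 659 to 801 CPM) rose in 688(A)T, and SFRP2 (-0.65) and KREMEN1 (-0.51) fell in 839T, with the same counts adjusted over the list alone. Their medians were -0.03 and -0.08 and their camera adjusted p-values 0.297 and 0.177. The Wnt ligand gene WNT2 and the Wnt receptor gene FZD4 fell in both lines, by values given with the shared genes.

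To find changes common to both lines, genes past the threshold in each were compared. Among genes with a mean of at least 5 CPM in each line, the 10 with the largest smaller rise were CXCL8, OASL, IFIT2, RAB27B, RRAD, the glycerol kinase gene GK, ITGA2, GPRC5A, MMP3 and the heme oxygenase gene HMOX1. HMOX1 rose from 141 ± 4.45 to 210 ± 26.5 CPM in 688(A)T (0.57, SE 0.09) and from 408 ± 24.2 to 644 ± 49.2 CPM in 839T (0.66, SE 0.09). RRAD rose by 0.63 and 0.77 and GK by 0.68 and 0.62. In 688(A)T, RAB27B rose by 0.66, ITGA2 by 0.62 and MMP3 by 0.59, and in 839T GPRC5A rose by 0.60. The 9 genes with the largest smaller fall after CD276 were HCCS, ATP6AP1, LONRF1, SVEP1 (-0.64 and -0.68), P3H1 (-0.92 and -0.63), FBLN5 (-0.59 and -0.62), DIPK1A (-0.82 and -0.58), FZD4 (-0.59 and -0.57) and WNT2 (-0.57 and -0.65). Of these 9 genes, 6 carry the GCGATAC heptamer in a transcript. In 688(A)T the ITGA2 call was lost in 9 of the 12 omissions of a library (adjusted p from 0.0524 to 0.142) and the MMP3 call without control replicate 3 (0.0568). In 839T the WNT2 call was lost in 5 (0.0503 to 0.119).

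**Figure D3:**
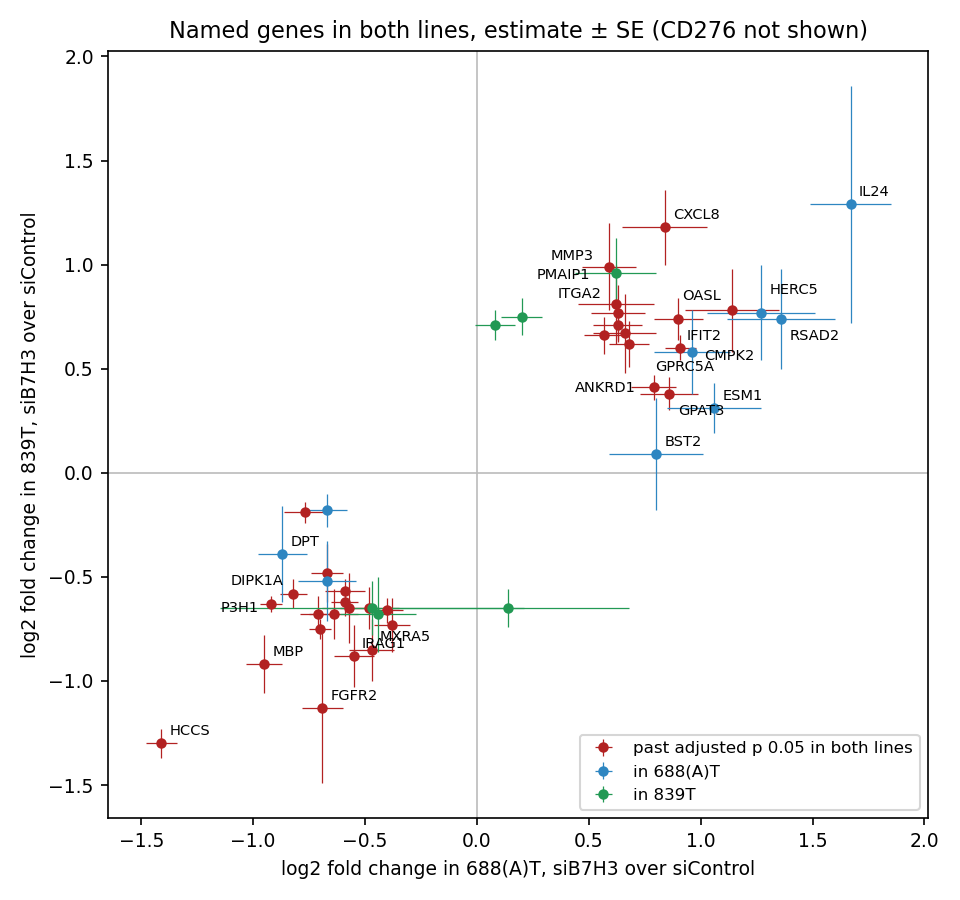
Log2 fold change, siB7H3 over siControl, of named genes in 688(A)T (horizontal axis) against 839T (vertical axis), with bars of 1 SE; red genes passed adjusted p 0.05 in both lines, blue in 688(A)T and green in 839T, and CD276 is left out. HCCS sits at -1.41 and -1.30 and CXCL8 at 0.84 and 1.18.

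Of the genes called in each line, 264 rose in both (57.2 would be shared if the calls were independent; Fisher's exact p = 1.48e-111) and 350 fell in both, CD276 included (83.2; p = 4.08e-138). Fisher's test takes genes as independent units, which correlated genes are not, so these p-values overstate the evidence. Opposite calls were fewer than independence gives, with 28 genes higher in 688(A)T and lower in 839T (73.5) and 6 the other way (64.7). Across 3566 genes called in at least 1 line, CD276 left out, log2 fold changes correlated with Pearson 0.49 and Spearman 0.54, and across all 15703 other genes with 0.20 and 0.27; genes are not independent replicates. The 614 genes that changed the same way became 369 without 839T siB7H3 replicate 1 and 392 without 688(A)T siB7H3 replicate 1. With the length and GC trend removed, 849 genes changed the same way. On average over both lines, 3241 genes changed, 1544 higher and 1697 lower, 24 of them at least 2-fold. In this average, 23 of 28 matrix genes fell and 1 rose (25 and 1 adjusted over the list alone; median -0.22, camera adjusted p = 7.57e-14, or adjusted p = 0.237 with an estimated correlation). Fibroblast markers, 4 of them in the same list, moved with them: 14 of 16 fell and 0 rose (14 and 0 adjusted over the list alone; median -0.22). Of 25 cytokine and NF-kB target genes 15 rose and 2 fell (16 and 2 adjusted over the list alone; median 0.30, adjusted p = 9.15e-07, or adjusted p = 0.0848 with an estimated correlation).

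To ask which effects differed between the lines, the effect in 839T was tested against that in 688(A)T. The stress-induced mTORC1 inhibitor gene DDIT4 had log2 fold changes of 0.22 in 688(A)T (adjusted p = 0.0526) and -0.57 in 839T (adjusted p = 2.04e-05), a difference of -0.79 (SE 0.11, adjusted p = 3.45e-04). The matrix gene TNXB differed by -0.77 (0.46 and -0.30), the splicing factor gene SRRM2 by -0.72 (0.29 and -0.43), the peptide hormone gene ADM2 by -0.71, the protease gene ADAMTS15 by -0.66 and the AP-1 gene FOSL1 by -0.65 (0.52 and -0.13). In the other direction, the steroid-reducing enzyme gene AKR1C2 differed by 0.68 (-0.29 and 0.40), the long noncoding RNA SMILR by 0.65 (-0.60 and 0.05), the aggrecan-cleaving protease gene ADAMTS5 by 0.64 (-0.09 and 0.55), the hormone gene STC1 by 0.64 (-0.31 and 0.32), the kinase gene SGK1 by 0.63 (-0.10 and 0.53) and ATF3 by 0.62 (0.08 and 0.71). In all, 332 genes differed, 124 more positive and 208 more negative in 839T, with a median absolute difference of 0.31. This balance turned with upper-quartile factors (190 and 168), with no low-count filter (546 and 256) and with the length and GC trend removed (188 and 158). The count was 151 without 688(A)T siB7H3 replicate 2, 199 without 688(A)T control replicate 1, 215 without 839T siB7H3 replicate 1 and 173 without 839T siB7H3 replicate 3, and the ADM2 call was lost without 688(A)T siB7H3 replicate 2 (adjusted p = 0.0725) or 3 (0.0529). Interferon-stimulated genes had a median difference of -0.35 (camera adjusted p = 5.09e-14, or adjusted p = 0.42 with an estimated correlation) and ribosomal protein genes one of 0.12 (adjusted p = 2.66e-06, or adjusted p = 0.42 with an estimated correlation).

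**Figure D4:**
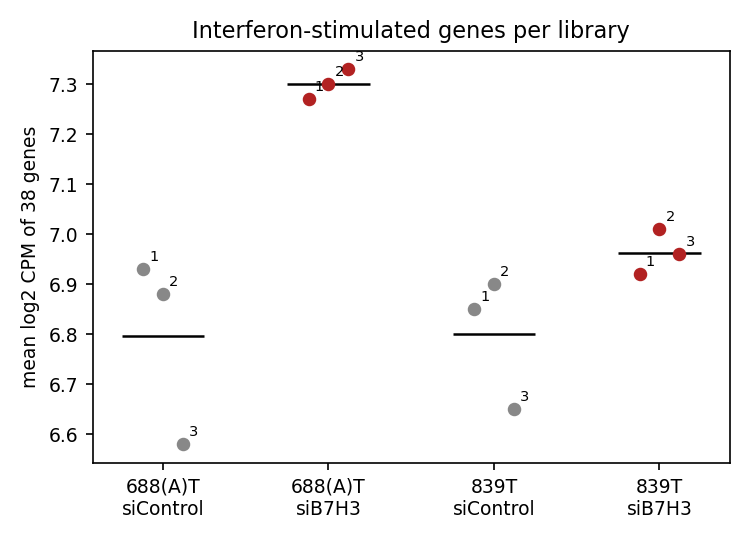
Mean log2 CPM of 38 interferon-stimulated genes (vertical axis) in each library of the 4 groups of line and siRNA; points carry replicate numbers and lines are group means. The siB7H3 libraries of 688(A)T lie between 7.27 and 7.33 and its controls between 6.58 and 6.93, and in 839T the siB7H3 libraries lie between 6.92 and 7.01 and the controls between 6.65 and 6.90.

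The control libraries gave the baseline difference between the lines. The cytokine-like gene CYTL1 had 0 counts in 688(A)T and 105 ± 9.89 CPM in 839T (n = 3 each), at least 4837-fold higher against a floor of 3 counts over the group. PI16 (0.0863 and 152 CPM), the retinol carrier gene RBP4 (0.101 and 76.8 CPM), the ephrin receptor gene EPHA5 (0.186 and 89.1 CPM), SCRG1 (0.0941 and 31 CPM) and TTC12 (0.0363 and 7.27 CPM) were also higher in 839T. TRH, the thyrotropin-releasing hormone gene, had 27.7 CPM and DHRS9 9.02 CPM in 839T, with 3 counts or fewer over the 688(A)T group. Conversely the surface glycoprotein gene EMB (15.8 ± 0.239 CPM), the neural crest transcription factor gene PAX3 (14.1 ± 0.857), the Wnt inhibitor gene APCDD1 (12.2 ± 0.228) and the noncoding RNA HOXB-AS3 (12 ± 0.728) had 0 counts in 839T, and were at least 488-, 435-, 376- and 369-fold higher in 688(A)T. The homeobox genes HOXB7 (22.8 CPM), HOXB3 (13.7), IRX1 (20.3) and IRX2 (24.5) had 3 counts or fewer over the 839T control group. Between the lines 9207 genes differed, 4602 higher and 4605 lower in 839T, and 2249 of them at least 2-fold. The first principal component, which separated the lines, held 94.2% of the variance, and the second, which separated the siRNAs, 2.8%.

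Marker genes of cell types gave a further view of both lines. Of 16 melanocyte lineage genes, the median was 0.0549 CPM in the 688(A)T controls and 0.0449 CPM in the 839T controls: the pigment gene PMEL had 0.843 and 0.783 CPM, the lineage transcription factor gene MITF 1.22 and 3.2 CPM, and SOX10 and S100B had 0 counts. Of 16 fibroblast genes, the median was 364 and 474 CPM, with the collagen gene COL1A2 at 14300 and 17300 CPM and the proteoglycan gene DCN at 464 and 978 CPM. Neural crest-like and undifferentiated melanoma genes had medians of 0.674 and 0.47 CPM, though AXL (389 and 634 CPM) and NT5E (1500 and 1670 CPM) were abundant. Medians were 0.45 and 1.66 CPM for keratinocyte, 0.145 and 0.406 for endothelial, 0.0152 and 0.0105 for leukocyte and 29 and 8.04 for smooth muscle and pericyte genes. After siB7H3, AXL (0.21), NT5E, EGFR and NES rose and AQP1 fell in 688(A)T, and WNT5A (0.23) rose in 839T. KRT18 and KRT14 rose in 688(A)T, DSP and KRT14 fell in 839T, VWF fell in 839T, and NOTCH3 fell in both lines (-0.41 and -0.45). Smooth muscle and pericyte genes gave 2 rises and 3 falls in 688(A)T and 1 of each in 839T. Called by edgeR, 0 melanocyte and 0 leukocyte genes changed in either line, and at an unadjusted p under 0.05 these were 1 and 0 in 688(A)T and 0 and 0 in 839T, with 0 by DESeq2.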

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

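Of the tests in this part, that of a response of 688(A)T that 839T lacks and that of the GCGATAC heptamer as a partial cause were chosen after the result was seen. The heptamer itself was picked from these data, and leaving out genes with CGATAC was chosen after they were seen, as were thinning and the removal of the length and GC trend as alternatives.

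Genes and lists are given here because the siRNA effect in 839T differed from that in 688(A)T by a test of the difference (edgeR for genes, camera for lists). There were 332 such genes. Among immune genes the difference was -0.39 for DDX60L, -0.35 for IRF7, -0.37 for PARP14, -0.30 for ADAR, -0.24 for EIF2AK2, 0.29 for NFKBIA and 0.29 for SOD2. Among stress and metabolic genes it was -0.79 for DDIT4, -0.71 for ADM2, -0.34 for PSAT1, -0.25 for PHGDH, 0.62 for ATF3, 0.64 for STC1, 0.63 for SGK1, 0.40 for INSIG1 and 0.68 for AKR1C2. Among matrix and adhesion genes it was -0.77 for TNXB, -0.66 for ADAMTS15, -0.40 for BGN, 0.64 for ADAMTS5, 0.29 for P3H1, 0.58 for JCAD and 0.49 for SFRP4. Cell cycle and signalling genes gave -0.54 for MKI67, -0.25 for CDC25B, -0.65 for FOSL1, -0.23 for KLF4, 0.45 for PIM1, 0.39 for SOCS2 and 0.55 for EVI2A. SRRM2 differed by -0.72, TNRC6A by -0.26, SMILR by 0.65 and RPL34 by 0.26. The ADM2 call was lost without 688(A)T siB7H3 replicate 2 (adjusted p = 0.0725) or 3 (0.0529), and the count was 151 without 688(A)T siB7H3 replicate 2, 173 without 839T siB7H3 replicate 3, 199 without 688(A)T control replicate 1 and 215 without 839T siB7H3 replicate 1.

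Of the 23 lists, 12 differed between lines with the preset correlation, and 0 with an estimated one, where 4 had an unadjusted p under 0.05 and fry called 4. Interferon-stimulated genes (adjusted p = 5.09e-14), MHC class I genes (0.00301), S phase genes (0.00301), G2/M genes (0.0393), matrix genes (0.00301), Wnt targets (0.046), the unfolded protein response and ATF4 targets (0.0125) and RNA interference genes (0.00301) were more negative in 839T. Ribosomal protein genes (2.66e-06), cholesterol synthesis genes (0.00851), autophagy and lysosome genes (0.0142) and p53 targets (0.0336) were more positive. With an estimated correlation the adjusted p-values ran from 0.192 to 0.757. Mitochondrially encoded mRNAs did not pass in the main fit but passed under 13 of the alternatives tried. Single libraries ended some calls. G2/M had adjusted p = 0.768 without 688(A)T control replicate 3, 0.326 without 688(A)T siB7H3 replicate 1, 0.217 without 839T siB7H3 replicate 2, 0.0797 without 839T control replicate 1 and 0.0648 without 839T control replicate 3. S phase had 0.145 without 688(A)T control replicate 3 and 0.0716 without 688(A)T siB7H3 replicate 1. Autophagy had 0.111 without 839T control replicate 3, the ATF4 list 0.0582 without 688(A)T control replicate 2 and matrix genes 0.0515 without 688(A)T siB7H3 replicate 3. The p53 list had 0.0544 without 688(A)T control replicate 3, 0.0515 without 688(A)T siB7H3 replicate 3, and 0.0578 without 839T control replicate 3 or siB7H3 replicate 2. The Wnt call was lost without 688(A)T control replicate 2 (0.0762) or 3 (0.0544) or siB7H3 replicate 3 (0.0873), and without 839T control replicate 1 (0.112) or 2 (0.063) or siB7H3 replicate 1 (0.0628) or 3 (0.0932).

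The 332 genes were weighed against depth and base composition, since the siB7H3 libraries had lower totals than the controls in 688(A)T and 2 of 3 had higher totals in 839T, and the difference between lines fell with transcript length (Spearman -0.23) and GC content (-0.23). With all libraries thinned to the smallest total, 281 genes passed, 238 of them the same genes in the same direction. With the length and GC trend removed, 346 passed, 199 of them the same genes in the same direction, which argues against depth or these trends as the whole cause, though they may account for part of it. Ribosomal protein genes, lower in 688(A)T, had a median of -0.14 that became -0.10 with the trend removed, and 15 of 34 were then still lower. A difference in how the lines respond stays open as a hypothesis.

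The rise of interferon-stimulated genes in 688(A)T was weighed against depth, a single low control and a response that 839T lacks. After thinning 31 of 38 genes were higher, as with all counts. Without 688(A)T control replicate 3 the median was 0.36 against 0.45 with all libraries, and 28 genes were higher. Both values argue against depth or a single low control as the whole cause. The groups differed in the siRNAs transfected as well as in CD276. A response to the siRNAs themselves therefore cannot be told apart here from a response to lower CD276. Whether 688(A)T responded more than 839T may depend on the test: all 38 differences were below 0 and their mean was -0.34 (95% t interval -0.66 to -0.03, 8 residual degrees of freedom), fry gave an unadjusted p of 0.0264 and an adjusted p of 0.0867, and camera with an estimated correlation an unadjusted p of 0.114, so this stays open.

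Genes lower in both lines were weighed against seed pairing of the siRNAs, by which an siRNA can lower other mRNAs. Of the 20 heptamers in 3 prime UTRs tied most to lower values, 4 lay in the CD276 mRNA against a mean of 3.1 over 10000 matched draws (p = 0.372 by permutation); the bound set for this test was wrong, since 17 of the 20 lay within the range of shuffled genes. The heptamer GCGATAC, in the CD276 3 prime UTR on chromosome 15 at 73713086 to 73713092, had the lowest z in 688(A)T (-10.1) and in 839T (-8.9). Its 67 carriers, chosen in 688(A)T, had a median of -0.10 in 839T, where matched draws gave -0.04 to 0.03. The draws were matched on 3 prime UTR length and GC content but not on the change in 688(A)T. Since changes were shared between lines, this comparison cannot part pairing from a shared response. Pairing of an siRNA through this heptamer may still be a cause of part of the fall. The siRNA sequences are not given in the sources used here, so no siRNA is known to carry it, and 3 of 13 CD276 transcripts hold the site. Direct pairing through GCGATAC as the whole cause is argued against by 270 genes lower in both lines without CGATAC in a transcript. Pairing through other seeds of the siRNAs, whose sequences are not known here, is not covered by this count. By independence 71.5 would be shared. Genes lowered indirectly need not carry the site, so this count cannot decide on an indirect effect of such pairing.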

How the results depend on the processing

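Thinning, removal of the length and GC trend and the omission of genes with CGATAC were chosen after the data were seen; the other alternatives were planned. CD276 had log2 fold changes from -3.82 to -3.66 over the alternatives other than omitted libraries. No named gene or list past the threshold in both the main fit and an alternative reversed direction. Some lists that did not pass turned with fry. The unfolded protein response list in 688(A)T was lower by camera and higher by fry (adjusted p = 0.841 and 0.945). MHC class I genes in 839T were higher by camera and lower by fry (adjusted p = 0.981 and 0.896). Of 212 called values of named genes, 170 kept call and direction under every alternative that gave one; over all alternatives 4435 values stayed past the threshold and 199 did not. Over 69 list results, 88 values were weaker, 49 stronger and 1496 the same.

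Counts moved by more than 1.5-fold as follows. At an adjusted p under 0.01, 1092 genes changed in 688(A)T and 812 in 839T, since the threshold is stricter. Genes differing between lines numbered 802 with no low-count filter and 570 with the replicate block; the cause was not tested. Lists called in 688(A)T numbered 17 with DESeq2 and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05 and fry called 16. Lists called in 839T numbered 2 with an estimated correlation and 6 with fry, and lists differing between lines 0 and 4. The cause of these moves was not tested.

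With 1 library left out, the arm with 2 libraries is assumed to vary like the others. Genes changed in 688(A)T then ran from 1248 (without control replicate 3) to 2449, and were 1417 without siB7H3 replicate 1. In 839T they ran from 944 (without siB7H3 replicate 1) to 1980, and were 1218 without control replicate 3. Genes differing between lines ran from 151 (without 688(A)T siB7H3 replicate 2) to 443, and genes changed the same way in both from 369 (without 839T siB7H3 replicate 1) to 631, with 392 without 688(A)T siB7H3 replicate 1.

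Whether replicate numbers pair the libraries stays open. Deviations from group means of control and siB7H3 libraries with the same number (9435 genes) correlated by 0.25, -0.12 and 0.16 in 688(A)T (replicates 1, 2 and 3) and by 0.23, -0.27 and 0.20 in 839T. Not every library correlated best with its own number. Among named genes, CXCL8, MMP3, PMAIP1, RAB27B, HMOX1 and SQSTM1 were highest in replicate 1 and lowest in replicate 3 in all 4 groups, and PDGFD and FZD4 the reverse, which hints at something shared by number. With the replicate block 2545 genes changed in 688(A)T, 2097 in 839T and 3391 on average.

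The balance of directions also depended on scaling and filter. Of the genes differing between lines, 37.3% were more positive in 839T, but 53.1% (190 and 168) with upper-quartile factors, 68.1% with no filter and 188 against 158 with the length and GC trend removed. In 688(A)T 46.9% of called genes were higher, and 31.2% (795 and 1750) with no filter. In 839T 43.7% were higher, and 51.2% (1023 and 974) with no filter. Thinned to the smallest total, 1940 genes changed in 688(A)T, 1472 in 839T and 2734 on average, so depth limits the count. The average and the difference between lines were not run with each line fitted alone, since both need the 2 lines.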

Other observations

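In this part, the test on melanocyte genes, the counts of genes with the GCGATAC heptamer and the omission of genes with CGATAC were chosen after the result was seen.

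Several genes lower in both lines carry the GCGATAC heptamer. Of 344 genes lower in both lines with an annotated transcript, 48 carry it anywhere in a transcript, and 1 of 260 genes higher in both does. The heptamer was picked for its tie to lower values in these same data, so these counts describe it and do not test it. Of the 9 named genes lower in both lines besides CD276, 6 carry it: the heme lyase gene HCCS, LONRF1, SVEP1, the collagen hydroxylase gene P3H1, DIPK1A and the Wnt receptor gene FZD4. MBP and JCAD, named among the largest falls in 688(A)T, also carry GCGATAC. Of the 10 named genes higher in both, 0 carry CGATAC. Without genes that carry CGATAC, 2057 genes changed in 688(A)T, 1590 in 839T and 522 the same way in both.

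Both lines express fibroblast genes at high levels and melanocyte genes near 0. Of 16 fibroblast genes, 10 were among the 1000 most abundant genes of the control libraries, and their lowest median over the 6 control libraries was 360 CPM. A minority of fibroblasts among pigmented melanoma cells might give this, but the highest median of the 16 melanocyte lineage genes over these libraries was 0.0721 CPM, where pigmented cells forming most of a culture would give far more. Undifferentiated melanoma cells and fibroblast-like cells stay open, and no test here parts them.

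Other splits of the libraries were compared with the real one. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and in each case 1 split, the real one, gave as large a result. The real values and the highest of the others were 2368 and 0 genes in 688(A)T, 1847 and 2 in 839T, 9207 and 0 between control lines, and 11 and 9 lists in 688(A)T and 12 and 11 lists in 839T. Over 100 of 200 splits of both lines, 1 gave as many genes changed on average (3241, highest other 507). Likewise 1 gave as many changed the same way (614, highest other 0), and both were the real split. The other splits mix siB7H3 and control libraries in at least 1 line, which widens the spread within groups. Low counts of genes there are thus built in, and these splits cannot exclude chance or a difference between cultures. Called lists were not few there, with a median over the other splits of 6 in 688(A)T and 5 in 839T. The number of lists called with the preset correlation thus hardly set the real split apart. For genes differing between lines 2 of 100 gave as many (332, highest other 587). That other split keeps 688(A)T as it is and exchanges 2 of 3 libraries in 839T. It can thus read part of the effect of 688(A)T as a difference. Why its count was above the real one was not tested.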
